A study of Mus musculus with 9 samples.

How the data were processed

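Liver RNA of 9 male mice, 5 on Western diet plus alcohol and 4 controls, was extracted with Trizol and made into libraries with the Collibri 3′ mRNA kit, per the labels' protocols. Such libraries read the 3′ ends of transcripts, so a count does not depend on transcript length. Samples were grouped by their titles, and library names in the labels tied each of the 9 columns to 1 sample. The labels give no batch. Each library was taken as 1 mouse, because the series' design gives 5 and 4 mice.

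Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.0 and cutadapt 1.18, aligned with STAR (version not given in the sources used here) to mouse build GRCm39 (mm39), counted with HTSeq 0.11.0 and handled with edgeR 3.28.1 in R 3.6.3. Whether counting used strand, and how multimapping reads were treated, is not given in the sources used here, so members of gene families with near-identical copies, overlapping genes and antisense genes are uncertain. The deposited values are a signal, CPM (read counts scaled to library size) adjusted by TMM by the authors, for 55253 gene symbols. The deposited columns summed to between 959495 and 1061154, as TMM-scaled CPM does. All positive values (100%, within a relative tolerance of 1e-06) were whole multiples of the smallest value of their column, so that whole reads could be recovered. Those reads gave the depths and the count-based alternatives. The file gives symbols without coordinates, and the reference at hand was of another build, so no coordinates are printed.

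Values were tested as log2(CPM + 1) with limma-trend (limma 3.58.1, R 4.3.3), two-sided, over genes with a mean of at least 1 CPM in the 9 libraries, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A fold change on this scale understates the change of low genes. Means are given in CPM with the SD and n = 5 or n = 4, and log2 fold changes with their standard error (SE) or 95% interval. Of 55253 symbols, 24607 had reads and 14759 were tested. At an unadjusted p under 0.05 there were 1798 genes.

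Before the data were examined, 37 lists of genes were fixed (pathways, stress and sex-biased programmes, and markers of liver and other cell types), of which 36 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, adjusted over the 36 lists, and again with an estimated correlation and with fry, whose directional test asks whether a list's genes move one way on balance. With the preset correlation 22 lists were called, 16 higher and 6 lower. The 3 calls that held with an estimated correlation were male-biased hepatocyte genes, lipid droplet and lipid uptake, and lipid-associated macrophage. Estimated correlations ran from 0.03 (adipocyte) to 0.61 (Kupffer cell), above the preset 0.01. Camera adjusted p-values at the preset correlation can therefore be far too small, and a list called only with that setting is a weaker result. Some lists share members, so their results are not independent. For nuclear-encoded oxidative phosphorylation the median (-0.02) and mean (-0.002) were negative and the test's direction was higher.

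Named genes were fixed by a rule set before the data were examined. It took the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 5 CPM and no overlap between the groups, leaving out clone-like names. It also took the 2 called members with the smallest p of each list, or, of a list without called members, its most abundant one. Cyp2e1, Adh1, Aldh2, Scd1, Cyp7a1, Col1a1, Trem2 and Fgf21 were named whatever their values, as was any gene a later test is about. Timd4, Cd163 and Hamp, other called members listed by name, the transcripts of other tissues and the genes that open the last part were chosen after their values were seen. Of the genes the rule takes, 2 are not reported here.

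The analysis was tested on simulated counts drawn from the real libraries' means and sizes, with 200 genes changed and 15051 genes tested. It recovered 22 of 79 genes changed 1.5-fold (27.8%), 43 of 76 changed 2-fold (56.6%) and 40 of 40 changed 4-fold (100%), with 6 false calls among 111. Genes were drawn independently of one another, so these figures do not cover variation between mice that genes share. At a depth of 3635860 to 6643645 reads, 1 read was worth 0.152 to 0.270 CPM, and 0 reads allowed a level of up to 0.455 to 0.809 CPM (3 reads). This floor covers counting error only.

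Alternatives fixed before the data were examined were pseudocounts of 0.25 and 5, no filter and a mean of at least 5 CPM, all libraries rescaled to one total, median-of-ratios scaling, quantile normalization, robust limma-trend, array weights, the replicate number as a block, leaving out each library, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. One was added after seeing the data: scaling by TMM factors recomputed on 108 hepatocyte-list genes. Scripts for figures used Python 3.11.15 and matplotlib 3.10.9.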

Results

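Gene expression was measured by 3′ mRNA sequencing in the livers of 9 male C57Bl/6J mice. Of these, 5 mice received a Western diet, a diet used to induce fatty liver in rodents, together with 10% alcohol in sweetened drinking water for 23 weeks from the age of 10 weeks, and 4 control mice received chow and tap water. Reads in genes numbered from 3635860 in WD+alcohol 1 to 6643645 in WD+alcohol 4, and from 5050763 in control 2 to 5910285 in control 3. Between 19082 and 19758 genes had reads in a library. All pairs of libraries differed by more than counting noise, with a chi-square per degree of freedom of at least 6.34. The first principal component held 28.9% of the variance, and all 5 WD+alcohol libraries lay on its positive side (2.07 to 42.1) and all 4 controls on its negative side (-22.1 to -16.7). WD+alcohol 1, the library with the fewest reads, lay furthest out at 42.1.

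The comparison asked how combined feeding of a Western diet and alcohol changed the liver transcriptome. Diet, alcohol and sweetening were given together, so the comparison measures their joint effect and no part of it separately. Of 14759 genes tested, 338 differed at an adjusted p under 0.05 (limma-trend), 238 higher and 100 lower with Western diet plus alcohol. Among these, 176 changed at least 2-fold, 127 higher and 49 lower, and this number was 84 with a pseudocount of 5 and 117 at a mean of at least 5 CPM. The number higher was 365 with all libraries rescaled to one total and 404 with scaling on hepatocyte-list genes, and with DESeq2 545 genes differed (370 higher, 175 lower). The values of the groups did not overlap for 313 of the 338 genes (92.6%), against 5.34% of all tested genes and 1.59% by chance. Since the 338 genes were called on these same values, a high share follows from the selection and is no separate support. The genes with the largest rises were Cidec, Ly6d, Cfd, Cidea, Cyp2b9, Gpnmb, Orm3 and Ifi27l2b, and among those with the largest falls were Hsd3b5, Slco1a1, Serpina1e, Mup12, Selenbp2, Cyp2b10 and Mup21. Without WD+alcohol 5 the count was 201 genes (139 higher, 62 lower), without control 1 the number higher was 148, and without control 2 the number lower was 59. Higher genes made up 70.4% of the calls, and 83.0% with scaling on hepatocyte-list genes, which moved the median log2 fold change of all genes to 0.16.

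**Figure D1:**
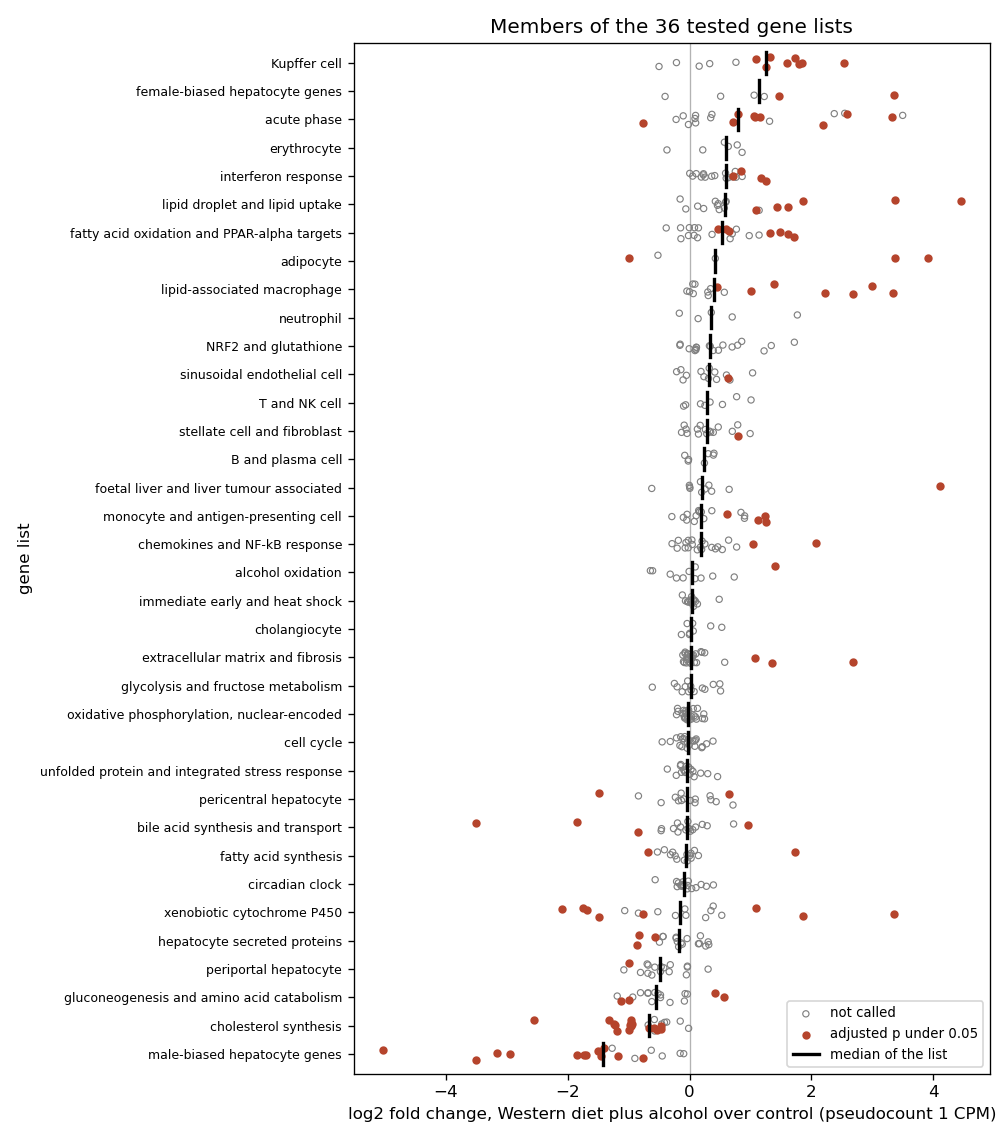
Each point is a tested member of a gene list, placed by its log2 fold change (x axis, Western diet plus alcohol over control, pseudocount 1 CPM). Filled points passed an adjusted p of 0.05, black lines are list medians, and the 36 lists (y axis) run from the lowest median, -1.43 for male-biased hepatocyte genes, to the highest, 1.26 for Kupffer cell genes.

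The list of lipid droplet and lipid uptake genes ranked above other genes with Western diet plus alcohol (camera adjusted p = 2.07e-14; adjusted p = 0.034 with an estimated correlation). Cidec, a lipid droplet fusion protein, averaged 74.5 ± 38.2 CPM (SD, n = 5) against 2.34 ± 1.75 CPM (SD, n = 4) in controls, and Cd36, a fatty acid transporter, averaged 73.6 ± 13.5 against 23.1 ± 3.33 CPM. Of 18 measured members, 6 rose (Cd36, Cidec, Plin4, Fabp4, Mogat1 and Cidea) and 0 fell, and 13 rose adjusted over the list alone (10 over all genes with DESeq2 and 3 without control 1). The call of Cidea was lost when any one of 7 libraries was left out (WD+alcohol 2, 3 or 5 or any control; adjusted p 0.0889 to 0.122), and with other filters, a pseudocount of 5 or robust limma-trend (0.0597 to 0.242). Genes of fatty acid oxidation and PPAR-alpha targets rose in 7 of 22 cases (9 adjusted over the list alone), with 0 lower. Vnn1, a pantetheinase, had a log2 fold change of 1.72 ± 0.21 (SE) and the peroxisomal thiolase Acaa1b one of 1.31 ± 0.16, while Fgf21 stood at 0.67 ± 0.32 and was not called (adjusted p = 0.432). The oxidation list was higher at a camera adjusted p of 2.70e-09, with adjusted p = 0.184 with an estimated correlation. Fatty acid synthesis genes were not called as a list (camera adjusted p = 0.0839; lower at an adjusted p under 0.05 in 4 of 22 alternatives, among them no filter, 0.0440, without control 1, 0.0259, and without WD+alcohol 5, 0.00849). Its 16 measured members included 1 that rose, the stearoyl-CoA desaturase Scd1, at 2918 ± 578 against 906 ± 322 CPM, and 1 that fell, the desaturase Fads1, at 144 ± 35.7 against 229 ± 25 CPM. Adjusted over the list alone, 1 rose and 4 fell. Fads1 was not called without control 1 or control 2 (adjusted p 0.0509 to 0.0566) or with scaling on hepatocyte-list genes (0.150). In the adipocyte list, 5 of 10 genes were measured, 2 rose (Cfd and Cidea) and 1 fell (Pck1), or 3 and 1 adjusted over the list alone. That list was not called (camera adjusted p = 0.393; 0.0480 with no filter), and Adipoq, Plin1, Lep, Retn and Adig were below the filter. Cfd, complement factor D, averaged 58.4 ± 50.9 against 1.45 ± 0.91 CPM (not called with robust limma-trend, adjusted p = 0.131).

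The cholesterol synthesis list was lower at a camera adjusted p of 2.33e-30, with adjusted p = 0.0527 with an estimated correlation. All 24 measured members had a negative log2 fold change (median -0.67), 16 fell at an adjusted p under 0.05, and 22 fell adjusted over the list alone. Cyp51, a sterol demethylase, averaged 60.7 ± 6.58 CPM against 120 ± 18.7 CPM in controls, and the cholesterol transfer protein Stard4 23.0 ± 2.26 against 46.5 ± 8.39 CPM. For bile acid synthesis and transport, 3 of 20 measured members fell (Cyp7b1, Slco1a1 and Cyp27a1) and 1 rose (Abcg5), the same numbers as adjusted over the list alone. Cyp7b1, an oxysterol hydroxylase, averaged 32.6 ± 12.1 against 115 ± 16.7 CPM, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 52.8 ± 29.1 against 30.2 ± 16.2 CPM without being called (adjusted p = 0.597). This list was lower at a camera adjusted p of 0.0368, but adjusted p = 0.601 with an estimated correlation, and the call was lost without WD+alcohol 2, WD+alcohol 5 or control 2 (adjusted p 0.109 to 0.491). It was also lost at a mean of at least 5 CPM (0.0655), with quantile normalization (0.0912) and with array weights (0.144). The median log2 fold change of the bile acid list was -0.04, and Cyp7b1 and Slco1a1 are also on the male-biased hepatocyte list.

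Male-biased hepatocyte genes fell. The median log2 fold change over 18 measured members was -1.43, all 18 were negative, 12 fell at an adjusted p under 0.05 and 16 fell adjusted over the list alone. Hsd3b5, a steroid dehydrogenase, averaged 1.78 ± 2.04 CPM (SD, n = 5) against 80.2 ± 43.3 CPM (SD, n = 4). Selenbp2, a selenium-binding protein, averaged 13.7 ± 6.29 against 110 ± 40.4 CPM, and the organic anion transporter Slco1a1 averaged 11.6 ± 6.81 against 124 ± 29.6 CPM. The list was lower at a camera adjusted p of 1.27e-26, and adjusted p = 0.0102 with an estimated correlation. Serpina1e (779 ± 708 against 5393 ± 1794 CPM), Mup12 (37.4 ± 25.8 against 237 ± 66.8 CPM) and Mup21 (26.3 ± 11.4 against 103 ± 24.5 CPM) also fell, and as members of families of near-identical copies their reads could be shared with paralogs. With robust limma-trend Serpina1e and Mup12 were not called (adjusted p 0.0599 and 0.1098). Of the female-biased list, 6 of 21 genes were measured and 2 rose, over all genes and adjusted over the list alone, with 0 lower (median 1.14). These were the cytochrome P450 Cyp2b9, at 13.9 ± 8.08 against 0.34 ± 0.55 CPM, and the monooxygenase Fmo2, at 17.9 ± 7.06 against 5.80 ± 2.59 CPM. The female-biased list was higher at a camera adjusted p of 6.57e-04, with adjusted p = 0.124 with an estimated correlation. Fmo2 was not called without control 1, control 3, WD+alcohol 3 or WD+alcohol 5 (adjusted p 0.0593 to 0.0724), nor with no filter (0.05004) or robust limma-trend (0.0848).

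Genes of alcohol oxidation were not called as a list (camera adjusted p = 0.679). The classical enzymes were not called either, with log2 fold changes of 0.09 (95% interval -0.26 to 0.44) for Cyp2e1, the inducible ethanol-oxidising P450, 0.09 (-0.28 to 0.47) for the alcohol dehydrogenase Adh1 and 0.19 (-0.08 to 0.45) for the acetaldehyde dehydrogenase Aldh2. Cyp2e1 turned to -0.03 without WD+alcohol 3, and Adh1 turned to -0.04 without control 3. Of 12 measured members, 1 rose (Aldh3a2, a fatty aldehyde dehydrogenase, at 350 ± 106 against 127 ± 17.5 CPM) and 0 fell, with 2 higher and 1 lower adjusted over the list alone. Over all genes, 2 members rose with all libraries rescaled to one total and with array weights. Xenobiotic cytochrome P450 genes moved both ways, with 3 of 18 higher (Cyp3a11, Cyp2b9 and Cyp2c38) and 5 lower (Cyp2c29, Cyp2b10, Cyp1a2, Cyp2d9 and Cyp2c54), or 4 and 8 adjusted over the list alone. Cyp3a11 averaged 1779 ± 514 against 474 ± 53.1 CPM, and Cyp2b10 averaged 1.70 ± 0.72 against 10.9 ± 5.54 CPM. As a list they were not called (camera adjusted p = 0.0703), but were lower at an adjusted p under 0.05 in 6 of 22 alternatives, among them all libraries rescaled to one total (0.0166), scaling on hepatocyte-list genes (0.00159), without control 3 (0.0434) and without WD+alcohol 3 (0.00131).

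**Figure D2:**
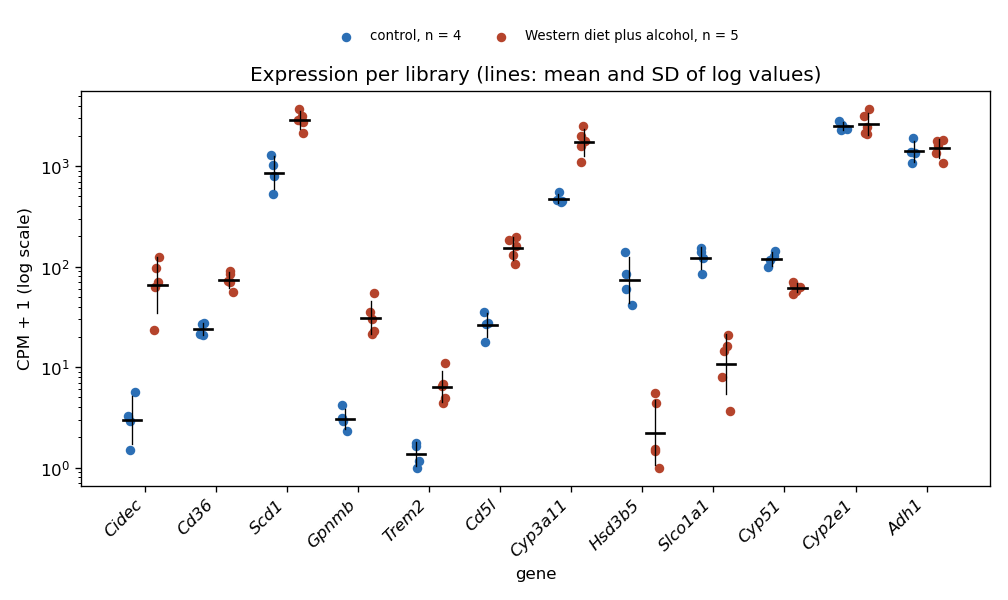
CPM plus 1 of 12 genes (x axis) in each library, on a log scale (y axis), for 4 control and 5 Western diet plus alcohol libraries, with the mean and SD of the log values as black lines. The groups do not overlap for Cidec, Cd36, Scd1, Gpnmb, Trem2, Cd5l, Cyp3a11, Hsd3b5, Slco1a1 and Cyp51, and they overlap for Cyp2e1 and Adh1.

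In the Kupffer cell list, 8 of 13 measured members rose (Cd5l, C1qc, C1qa, C1qb, Folr2, Vsig4, Cd207 and Clec4f), 0 fell, and the numbers were the same adjusted over the list alone. Cd5l, a secreted macrophage protein, averaged 155 ± 38 against 26.0 ± 7.14 CPM, and the complement subunit C1qc 75.5 ± 17.9 against 20.1 ± 4.41 CPM. Log2 fold changes of the Kupffer markers Timd4 (-0.22 ± 0.29, SE) and Cd163 (-0.50 ± 0.29, SE) had the opposite sign and were not called (adjusted p = 0.843 and 0.542). The list was higher at a camera adjusted p of 6.45e-13, with adjusted p = 0.150 with an estimated correlation. Lipid-associated macrophage genes rose in 7 of 16 cases (Gpnmb, Mmp12, Lpl, Cd68, Trem2, Atp6v0d2 and Ctsd) and fell in 0, with 8 higher adjusted over the list alone. Gpnmb, a lysosomal membrane glycoprotein, averaged 31.8 ± 13.2 against 2.11 ± 0.77 CPM, the elastase Mmp12 14.8 ± 4.76 against 1.39 ± 0.30 CPM, and the lipid receptor Trem2 5.71 ± 2.59 against 0.40 ± 0.37 CPM. This list was higher at a camera adjusted p of 6.92e-14, and adjusted p = 0.034 with an estimated correlation. Monocyte and antigen-presenting cell genes included 4 higher of 19 (Lyz2, Adgre1, Csf1r and Plac8) and 0 lower, or 6 higher adjusted over the list alone (2 over all genes without control 1 or WD+alcohol 5). Lysozyme 2 (Lyz2) averaged 229 ± 51.3 against 103 ± 7.58 CPM and Adgre1, encoding F4/80, 21.7 ± 4.92 against 8.50 ± 1.26 CPM. The camera adjusted p was 8.25e-07, and adjusted p = 0.163 with an estimated correlation.

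No neutrophil gene was called among 5 measured (2 higher adjusted over the list alone, 2 over all genes with scaling on hepatocyte-list genes, and 1 with DESeq2, with all libraries rescaled to one total and without WD+alcohol 1, control 3 or control 4). S100a9, a calcium-binding protein of neutrophils, averaged 20.03 ± 3.05 against 12.3 ± 3.86 CPM without being called (adjusted p = 0.0886). It was called with DESeq2 (adjusted p = 0.0262), with scaling on hepatocyte-list genes (0.0321) and without control 4 (0.0490). The neutrophil list was higher at a camera adjusted p of 0.0473, with adjusted p = 0.323 with an estimated correlation, and it was not called without WD+alcohol 2, 4 or 5, control 1 or control 2 (adjusted p 0.0537 to 0.175). Its call also ended with a pseudocount of 5, all libraries rescaled to one total, quantile normalization, array weights and DESeq2 (0.0539 to 0.0699). Among 8 measured T and NK cell genes 0 were called, or 2 higher adjusted over the list alone and 1 over all genes with DESeq2, with scaling on hepatocyte-list genes, with all libraries rescaled to one total or without WD+alcohol 2, and Gzmb had a log2 fold change of -0.10, which was 0.07 with scaling on hepatocyte-list genes. The T and NK cell list was higher at a camera adjusted p of 0.0209, with adjusted p = 0.254 with an estimated correlation, and was not called without control 1, WD+alcohol 4 or WD+alcohol 5 (adjusted p 0.0514 to 0.109). Of 7 measured B and plasma cell genes 0 were called, over all genes or adjusted over the list alone (camera adjusted p = 0.301), and Igkc averaged 199 ± 16.8 against 211 ± 24.8 CPM. Chemokine and NF-kB response genes included 2 higher of 22, the chemokine Ccl6 (41.7 ± 14.7 against 8.74 ± 0.97 CPM) and the adhesion molecule Vcam1 (49.2 ± 11.9 against 23.0 ± 3.69 CPM), 0 lower, and 3 higher adjusted over the list alone. The chemokine list was higher at a camera adjusted p of 0.00315, with adjusted p = 0.226 with an estimated correlation, and its adjusted p was 0.0654 without control 2. All 20 measured interferon response genes had a positive log2 fold change, 4 rose (Ifi44, Ifit3, Oasl2 and Bst2), and 10 rose adjusted over the list alone. The number called was 8 with scaling on hepatocyte-list genes, 7 with DESeq2, 2 at a mean of at least 5 CPM or without control 4, 1 with no filter and without control 1 or WD+alcohol 3, and 0 without control 3 or WD+alcohol 5. Ifi44 averaged 7.90 ± 2.36 against 2.74 ± 1.26 CPM and Ifit3 10.5 ± 1.84 against 4.40 ± 2.16 CPM. The interferon list was higher at a camera adjusted p of 1.00e-10, with adjusted p = 0.0841 with an estimated correlation. Leaving out control 1, control 3, control 4 or WD+alcohol 5 ended the call of Ifi44 (adjusted p 0.0513 to 0.0614), and leaving out WD+alcohol 1, 3 or 5, control 1 or control 3 ended that of Ifit3 (adjusted p 0.0537 to 0.0877; 0.0621 with no filter).

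Acute phase genes were higher in 8 of 21 cases (Orm3, Saa3, Hpx, Orm2, Hp, Orm1, Lbp and Apcs) and lower in 1, Hamp, the gene of the iron-regulating hormone hepcidin. Adjusted over the list alone, 11 were higher and 1 was lower. The orosomucoid Orm3 averaged 77.9 ± 28.5 against 7.60 ± 4.87 CPM, serum amyloid Saa3 averaged 51.1 ± 27.8 against 9.55 ± 2.16 CPM, and Hamp averaged 593 ± 148 against 999 ± 178 CPM. The list was higher at a camera adjusted p of 1.01e-09, with adjusted p = 0.226 with an estimated correlation. Hamp was not called without WD+alcohol 2, 3 or 5 or control 1, 3 or 4 (adjusted p 0.0560 to 0.106), with no filter (0.0708), with scaling on hepatocyte-list genes (0.120) or with robust limma-trend (0.138). The number of acute phase genes higher was 4 with robust limma-trend, and 5 with no filter and without control 1, WD+alcohol 4 or WD+alcohol 5. Orosomucoid genes are near-identical copies, and their reads could be shared.

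The periportal list was lower at a camera adjusted p of 3.24e-08, with adjusted p = 0.170 with an estimated correlation. The gluconeogenesis list was lower at a camera adjusted p of 2.31e-06, with adjusted p = 0.251 with an estimated correlation. Both lists hold Hal, Sds, Gls2, Arg1, Ass1, Asl, Cps1 and Pck1, so their falls are not separate results. Of 17 measured periportal genes 16 had a negative log2 fold change, 1 fell (Pck1, phosphoenolpyruvate carboxykinase, at 935 ± 115 against 1914 ± 544 CPM), and 7 fell adjusted over the list alone, with 0 higher. The number lower was 7 with DESeq2, 4 with all libraries rescaled to one total, 3 with scaling on hepatocyte-list genes, 5 without WD+alcohol 4, 3 without control 1 and 2 without control 4. Gluconeogenesis and amino acid catabolism had 2 lower (Agxt and Pck1) and 2 higher (Pcx and Fbp1) of 18, or 11 lower and 2 higher adjusted over the list alone; lower were 7 with DESeq2, 6 without WD+alcohol 4, 5 without control 1 or with all libraries rescaled to one total, and 4 with scaling on hepatocyte-list genes. Agxt, a glyoxylate aminotransferase, averaged 37.2 ± 9.49 against 80.9 ± 14.7 CPM, and pyruvate carboxylase Pcx 122 ± 9.91 against 82.8 ± 7.84 CPM. Pericentral genes were not called as a list (camera adjusted p = 0.752), with 1 of 16 lower (Cyp1a2, 128 ± 47.2 against 349 ± 68.0 CPM) and 1 higher (glutamine synthetase Glul, 811 ± 147 against 513 ± 75.7 CPM), or 3 lower and 2 higher adjusted over the list alone. With all libraries rescaled to one total, 2 pericentral genes were higher and 1 lower. Glul was not called without control 1 or WD+alcohol 5 (adjusted p 0.0597 to 0.0685). Among 19 hepatocyte secreted proteins 3 fell (Serpina1a, Apoa1 and Alb) and 0 rose, or 5 adjusted over the list alone. Serpina1a averaged 655 ± 140 against 1176 ± 150 CPM and apolipoprotein Apoa1 3436 ± 580 against 5019 ± 382 CPM. This list was lower at a camera adjusted p of 0.00526, with adjusted p = 0.562 with an estimated correlation, and was not called without WD+alcohol 2 or control 2 (adjusted p 0.0800 to 0.129) or with quantile normalization (0.289). The number of members lower was 5 with DESeq2, and 1 with no filter, quantile normalization or scaling on hepatocyte-list genes and without WD+alcohol 1, 2 or 5 or any control. The call of Apoa1 was lost when WD+alcohol 1, 2 or 5 or any control was left out (adjusted p 0.0689 to 0.117), and with no filter, quantile normalization or scaling on hepatocyte-list genes (0.0660 to 0.330).

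NRF2 and glutathione genes were positive in 16 of 19 cases, 0 were called and 6 rose adjusted over the list alone, and the list was higher at a camera adjusted p of 1.15e-05 (adjusted p = 0.226 with an estimated correlation). The count of 0 was 7 with scaling on hepatocyte-list genes, 5 with DESeq2, 2 with all libraries rescaled to one total, 7 without WD+alcohol 4 and 1 without WD+alcohol 2 or control 4. Gstm1, a glutathione transferase with close paralogs, averaged 1488 ± 607 against 861 ± 173 CPM without being called (adjusted p = 0.268), and was called without WD+alcohol 4 (adjusted p = 0.0389) and with scaling on hepatocyte-list genes (adjusted p = 0.0243). The remaining lists had 0 called members, over all genes and adjusted over the list alone, and none was called by camera. These were glycolysis and fructose metabolism (15 measured, camera adjusted p = 0.679), the unfolded protein and integrated stress response (18, 0.413), nuclear-encoded oxidative phosphorylation (26, 0.975), the circadian clock (17, 0.451), immediate early and heat shock genes (15, 0.413), cholangiocyte genes (8, 0.555) and the cell cycle (22, 0.731). In the alternatives other than the 0 called were 1 immediate early gene with DESeq2, 1 each of the immediate early and unfolded protein lists without WD+alcohol 4, and 2 unfolded protein and 1 glycolysis genes without control 4. Log2 fold changes of the most abundant members of the other lists, from the unfolded protein response to the cell cycle, were -0.15 for Hspa5, 0.06 for Uqcrq, -0.13 for Tef, -0.02 for Hsp90aa1, 0.06 for Spp1 and 0.20 for Ccnd1. With scaling on hepatocyte-list genes Hspa5, Tef and Hsp90aa1 were positive, at 0.03, 0.04 and 0.16. Hsp90aa1 was also positive with all libraries rescaled to one total (0.04), with quantile normalization (0.01), without control 3 (0.02) and without WD+alcohol 3 (0.009), and Tef without WD+alcohol 2 (0.01) or control 2 (0.07).

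Most matrix genes were not called, with 3 higher of 28 measured, over all genes and adjusted over the list alone, and 0 lower. These were Mmp12, the collagen Col14a1 (25.6 ± 7.22 against 11.7 ± 3.76 CPM) and the proteoglycan Lum. The matrix list was not called (camera adjusted p = 0.0617; median log2 fold change 0.02), and was called in 13 of 22 alternatives, among them without WD+alcohol 1, 3, 4 or 5, control 1 or control 3 (adjusted p 0.0146 to 0.0491). Without control 1, control 3 or WD+alcohol 5, Col14a1 was not called (adjusted p 0.0540 to 0.0593) and 1 matrix gene was higher. Col1a1, a fibrillar collagen, averaged 1972 ± 151 against 2075 ± 108 CPM, a log2 fold change of -0.08 (95% interval -0.26 to 0.11), which was 0.10 with scaling on hepatocyte-list genes. Of 17 stellate cell and fibroblast genes, 1 rose (the proteoglycan Dcn, 163 ± 29.9 against 93.0 ± 14.3 CPM), 0 fell, and 2 rose adjusted over the list alone (3 over all genes with scaling on hepatocyte-list genes). The stellate list was higher at a camera adjusted p of 0.00271, with adjusted p = 0.226 with an estimated correlation. Sinusoidal endothelial genes had 1 higher of 14 (the Fc receptor Fcgr2b, 30.1 ± 3.83 against 19.02 ± 2.97 CPM), 0 lower, and 4 higher adjusted over the list alone (2 over all genes with all libraries rescaled to one total). This endothelial list was higher at a camera adjusted p of 0.00215, with adjusted p = 0.274 with an estimated correlation, and Fcgr2b was not called without control 3 or WD+alcohol 5 (adjusted p 0.0544 to 0.0577). In the list of foetal liver and liver tumour genes 1 of 11 rose, over all genes and adjusted over the list alone, Ly6d at 47.5 ± 36.4 against 0.95 ± 0.64 CPM (not called with robust limma-trend, adjusted p = 0.0680), and 0 fell. That list was higher at a camera adjusted p of 0.0129, with adjusted p = 0.254 with an estimated correlation, and was not called without WD+alcohol 2 or control 2 (adjusted p 0.0780 to 0.0800). Erythrocyte genes had 0 called of 6, over all genes and adjusted over the list alone, but 3 higher with scaling on hepatocyte-list genes, with Hba-a1 at 675 ± 135 against 573 ± 51.7 CPM. The erythrocyte list was higher at a camera adjusted p of 0.0368, with adjusted p = 0.414 with an estimated correlation, and was not called without control 1, control 2, WD+alcohol 3 or WD+alcohol 5 (adjusted p 0.0840 to 0.107), with DESeq2 (0.0569) or at a mean of at least 5 CPM (0.0831). The pancreas list had 1 measured gene of 11, too few to test as a list, and this gene, the elastase Cela1, fell from 17.1 ± 6.37 to 6.51 ± 0.94 CPM.

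Several transcripts that are not typical of liver had high and nearly constant levels in all 9 libraries. Col1a1 lay between 1859 and 2217 CPM, Col1a2 between 2089 and 2583 CPM, the mast cell protease Cpa3 between 677 and 859 CPM, and Hmga2, a gene of embryonic and proliferating cells, between 190 and 239 CPM. Xist, the RNA of the inactive X chromosome in female cells, lay between 92.9 and 132 CPM (360 to 758 reads) in these libraries labelled male, which also held Y-linked Ddx3y at 28.3 to 46.2 CPM. Igkc of the B and plasma cell list (175 to 231 CPM) and Spp1 of the cholangiocyte list (112 to 133 CPM) also varied little. The source of these transcripts was not determined. Whether it also added reads to the matrix, stellate, cell cycle, immediate early, lymphocyte, cholangiocyte or other lists was not determined either. Flat levels in those lists may therefore not describe the liver's own cells.

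**Figure D3:**
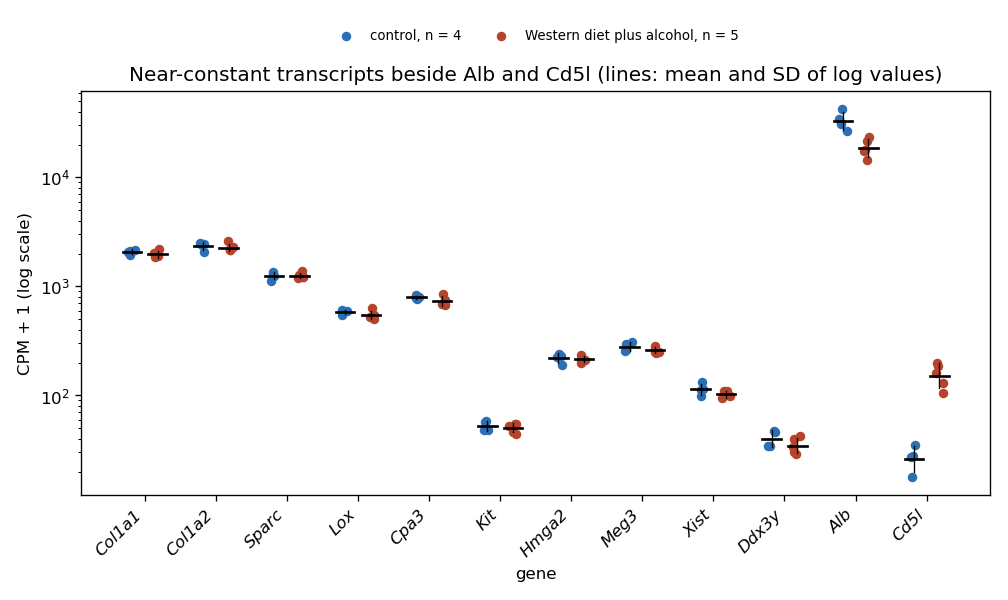
CPM plus 1 (y axis, log scale) of 12 genes (x axis) in 4 control and 5 Western diet plus alcohol libraries, with the mean and SD of the log values as black lines. Xist lies between 92.9 and 132 CPM in all 9 libraries, while Cd5l ranges from 16.9 to 197 CPM.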

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

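Values per library of the named genes, the number of reads and the number of genes with reads were compared within each group, and 7 of 174 groups of values held a library whose distance from the nearest other was above Dixon's 95% critical value (4.02%). Chance gives about 1 in 20. In the controls, Cyp3a11 was 553 CPM in control 3 against at most 454 CPM in the others, Ifi44 was 4.62 CPM in control 2 against at most 2.27 CPM, and control 1 had 19363 genes with reads against at most 19151. Fgf21 was at 0 in control 3, where 0 reads allow up to 0.521 CPM, against at least 1.32 CPM in the other controls. In the Western diet plus alcohol group, Fads1 was 206 CPM in WD+alcohol 5 against at most 137 CPM, and Pparg was 18.4 CPM in that library against at most 12.2 CPM. Fcgr2b was 23.5 CPM in WD+alcohol 2 against at least 30.5 CPM in the others.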

How the results depend on the processing

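The 338 called genes shared 306 of 315 genes with edgeR and 335 of 545 with DESeq2 (370 higher, 175 lower) on the recovered reads, all in the same direction. Fewer of the 338 stayed called when a library was left out, from 195 (without WD+alcohol 5) to 301 (without WD+alcohol 4). With the replicate block 109 of them did. With all libraries rescaled to one total 365 genes were higher, and with scaling on hepatocyte-list genes, added after seeing the data, 404. With at least a 2-fold change there were 117 genes at a mean of at least 5 CPM, where fewer genes are tested, and 84 with a pseudocount of 5, which shrinks the folds of low genes. For the other settings above the cause was not tested. Without single libraries the counts ranged from 201 to 387 genes, 139 to 264 higher, 59 to 123 lower, 122 to 205 with at least a 2-fold change, 12 to 17 lists higher and 4 to 7 lower. Without WD+alcohol 5 there were 201 genes (139 higher, 62 lower), without control 1 148 higher, and without control 2 59 lower. The 16 higher and 6 lower lists became 2 and 1 with an estimated correlation, which is larger than the preset one, and 7 and 2 with fry. Higher by fry were lipid droplet, fatty acid oxidation, interferon, lipid-associated macrophage, Kupffer, monocyte and female-biased genes (fry adjusted p 6.71e-04 to 0.0468). Lower by fry were cholesterol synthesis (fry adjusted p = 0.00407) and male-biased genes (2.63e-04). Outside the estimated correlation and fry, 15 of the 22 list calls held in every one of 22 alternatives. All of these alternatives kept the preset correlation, so they do not test that setting.

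Of 85 named genes, 64 were called. Over the alternatives these gave 1407 values, 1291 with the same call, 116 no longer past the threshold and 0 reversed, and 36 genes kept their call throughout. Only genes that were not called changed sign, each by little. With scaling on hepatocyte-list genes the log2 fold change was 0.025 for Hspa5, 0.040 for Tef, 0.16 for Hsp90aa1, 0.069 for Gzmb, 0.095 for Igkc, 0.099 for Col1a1 and 0.016 for Xist. Hsp90aa1 was 0.039 with one total for all libraries and 0.014 with quantile normalization. Leaving out single libraries gave -0.042 to 0.023 for Hsp90aa1 (positive without control 3, and 0.0095 without WD+alcohol 3) and -0.38 to 0.069 for Tef (positive without control 2, and 0.011 without WD+alcohol 2). It gave -0.033 (without WD+alcohol 3) to 0.18 for Cyp2e1 and -0.037 (without control 3) to 0.24 for Adh1. The cause of these sign changes was not tested.

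Groups share the replicate numbers 1 to 4. Deviations of same-numbered libraries correlated at -0.008, -0.31, -0.21 and -0.01, with the own number ranking 3, 4, 4 and 2 among the 4 controls, so the numbers were not taken as pairs. Only WD+alcohol 5 has the number 5, so a replicate block in effect leaves that library out, which without a block gave 201 genes. With the replicate block 112 genes were called (76 higher, 36 lower, 91 with at least a 2-fold change). Among the lists, bile acid synthesis (adjusted p = 0.102) and hepatocyte secreted proteins (0.0729) were then not called, and fatty acid synthesis (lower, 0.00538) and matrix (higher, 0.0380) were.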

Other observations

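The tests of other splits of the libraries were fixed after the counts of the real grouping were known and before any other split was examined. All other tests here, and the genes named first, were chosen after the values were seen. Those genes lie outside the fixed lists and were tested singly, not as groups. Cathepsin S (Ctss) averaged 117 ± 18.9 CPM (SD, n = 5) against 51.2 ± 4.03 CPM (SD, n = 4), the signalling adaptor Tyrobp 71.6 ± 7.65 against 44.7 ± 4.00 CPM, the Fc receptor Fcgr3 14.8 ± 3.88 against 7.10 ± 1.32 CPM, and the scavenger receptor Msr1 9.27 ± 3.68 against 2.83 ± 0.32 CPM. The Fc receptor chain Fcer1g averaged 61.5 ± 12.5 against 40.2 ± 2.93 CPM, but was not called without WD+alcohol 1, control 1, control 2 or control 3 (adjusted p 0.0536 to 0.0876). Pparg, a regulator of lipid storage, averaged 12.5 ± 3.35 against 5.19 ± 2.24 CPM, the apolipoprotein Apoa4 701 ± 417 against 89.8 ± 28.4 CPM, and the keratin Krt8 50.6 ± 16.01 against 19.95 ± 6.52 CPM; with robust limma-trend Apoa4 and Krt8 were not called (adjusted p 0.0517 and 0.0652). Gdf15, a stress-induced hormone, averaged 12.99 ± 3.77 against 5.70 ± 1.54 CPM and was not called without WD+alcohol 1, 2 or 5, control 3 or control 4 (adjusted p 0.0525 to 0.0683).

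Others outside the lists were lower. Cystathionine beta-synthase (Cbs), which takes homocysteine towards cysteine, averaged 167 ± 30.1 against 318 ± 58.7 CPM. Cth, the next enzyme of that path, averaged 72.6 ± 6.06 against 126 ± 41.1 CPM, and its call was lost without any one library except control 4 (adjusted p 0.0580 to 0.130) and in 6 alternatives that kept all libraries, outside the replicate block (0.0526 to 0.143). Coagulation factor F11 averaged 5.81 ± 1.66 against 17.1 ± 2.05 CPM, plasma prekallikrein (Klkb1) 112 ± 30.4 against 216 ± 35.9 CPM (adjusted p = 0.0790 with robust limma-trend), and the complement component C8b 48.3 ± 29.7 against 118 ± 26.6 CPM. C8b was not called without WD+alcohol 1, 2 or 5, control 2 or control 3 (adjusted p 0.0525 to 0.0704), with edgeR, DESeq2 or robust limma-trend (0.0510 to 0.169).

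Of 126 ways to split the libraries into 5 and 4, 100 were examined, the real one included. For 338 genes, 238 higher genes and 176 genes with at least a 2-fold change, 1 of the 100 splits, the real one, gave as many, and the highest of the others gave 151, 50 and 84. The 100 lower genes were matched by 2 of the 100 splits, and the highest other gave 101. That split set control 1 to 4 and WD+alcohol 4 against the remaining 4 libraries, nearly the real grouping turned round, so its lower genes were higher in 4 Western diet plus alcohol libraries. Chance is unlikely for these 4 counts, but 100 splits cannot go below 1 in 100. The splits also cannot tell the treatment from a batch, which the labels do not give. For the 16 higher lists 1 of 100 splits gave as many, so chance is unlikely there too, although the highest other gave 15. That other split set WD+alcohol 1, 2, 3 and 5 and control 4 against the rest, close to the real grouping, and the median of the other splits was 5. For the 6 lower lists 48 of 100 splits gave as many, so chance is not excluded for that number. There too the median of the other splits was 5. The highest other gave 16, with control 1 to 4 and WD+alcohol 3 against the rest, again nearly the real grouping turned round. With medians of 5 in both directions, list calls at the preset correlation were common under other groupings, some of them near the real one. A list's camera adjusted p at that correlation is therefore no reliable error rate. The splits tested the counts and not single lists.

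Several transcripts of mast cells, fibroblasts and proliferating cells were nearly constant in all 9 libraries, but not all markers of these cells were present. Of mast cell genes, Cpa3 averaged 760 CPM, Kit 50.7 CPM, Gata2 31.8 CPM, Ms4a2 28.8 CPM and Hdc 8.0 CPM, while Tpsab1 had 0 to 2 reads in a library, and of embryonic genes Hmga2 averaged 217 CPM while Lin28b had 0 reads. Of melanocyte genes Tyr, Tyrp1 and Mlana had 0 reads in every library, Pmel 0 to 4 and Dct 1 to 38 reads (up to 6.60 CPM), and myoblast Myod1, Myog, Myf5 and Chrna1 had 0 reads. Xist had at least 360 reads in each library, above the 3 reads of the floor, and Y-linked Ddx3y at least 105, which argues against cells of these male livers as the only source. RNA or reads of one outside source, in a like share of every library, are a candidate explanation. Such a source would need a small spread between libraries. It was taken over list genes with a mean of at least 50 reads. Beyond counting error, the spread within groups had a median of 8.01% for 60 matrix, cell cycle and immediate early genes. For 39 hepatocyte secreted, Kupffer and sinusoidal genes it was 18.4%, a ratio of 0.436 (95% bootstrap interval 0.372 to 0.506). In the controls alone the ratio was 0.376 (0.265 to 0.499), and both intervals come from resampling genes, not mice. Col1a1 and Col1a2, seen to be near-constant before the test was chosen, are on the matrix list. A spread this small is also not special to the matrix, cell cycle and immediate early genes. The median over 4186 genes with a mean of at least 200 reads, a higher limit than the 50 reads for the lists, was 7.73%. The ratio therefore cannot decide for such a source, and the source and its share were not determined.

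The Kupffer cell list was higher with the preset correlation (8 of 13 genes called) and with fry (adjusted p = 0.0148). With an estimated correlation it was not called (camera adjusted p = 0.150), and Timd4 and Cd163 had negative log2 fold changes (-0.22 and -0.50). A lower share of hepatocyte RNA may account for part of the rise, since it would raise all other cell types alike. Median log2 fold changes of the other tested cell type lists outside hepatocytes ran from 0.03 (cholangiocyte) to 0.60 (erythrocyte), against 1.26 for Kupffer genes. Scaling on hepatocyte-list genes moved the median of all genes to 0.16, a shift smaller than the Kupffer median. With that scaling the Kupffer list was still called at the preset correlation. The Kupffer median exceeded the sinusoidal endothelial median by 0.944 on the log2 scale. Its 95% bootstrap interval, from resampling genes and not mice, was -0.05 to 1.49 and holds 0. The explanations cannot be told apart with lists of 13 and 14 genes, and more macrophages, or more of these transcripts per macrophage, with the diet and alcohol also stay open and untested.

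Male-biased hepatocyte genes were lower, and 2 technical explanations were examined. A lower share of hepatocyte RNA would lower the secreted proteins of the same cells alike. The male-biased median lay below theirs, with a difference of -1.25 (95% bootstrap interval -1.68 to -0.68). Reads shared between paralogs would leave members outside the large families near 0. The median of 7 such members was -1.50 (-1.73 to -0.63), and 4 of them were called. Both intervals come from resampling genes as if they were independent, so they do not measure the spread between mice. Constant reads of an outside source, if there is one, would leave a fold understated only for genes that it adds reads to. Which genes these are was not determined, and Hsd3b5 was at 0 CPM in WD+alcohol 5. A hypothesis, on which these 2 tests and that of the list against other genes bear (camera adjusted p = 1.27e-26; adjusted p = 0.0102 with an estimated correlation), is that Western diet plus alcohol lowers the male expression programme of hepatocytes, and which of diet and alcohol does so was not tested and needs mice given each alone.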
